A study of Homo sapiens with 16 samples.

How the data were processed

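RNA was extracted with a column kit and poly-A RNA was made into TruSeq libraries, per the labels' protocols. The authors deposited 1 table of raw counts per library, 16 in all. Per the file headers, the tables of experiment 1 list Ensembl genes with their exon coordinates, strand and length beside a count, a layout that featureCounts writes, and those of experiment 2 list gene symbols with a count. Aligner, counter and their versions, and whether counting used strand, are not given in the sources used here. The submitters' processing notes name the build hg19, while the coordinates in the experiment 1 files are those of GRCh38: 96.3% of the 56898 genes that are also in GENCODE release 29 had the same start and end there. Coordinates in the text are those of the experiment 1 files. In experiment 2 all 26 values of 7 or more digits end in 0, so the largest counts there appear rounded.

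The experiments were joined by gene symbol, taken for the Ensembl genes from a table of gene names. Of 57500 genes in experiment 1 and 28890 in experiment 2, 28682 were joined 1 to 1, 28443 directly and 239 through an older symbol, and 14 symbols were left out as ambiguous. The joined genes held between 97.89% and 98.88% of each library's counts. Overlapping genes and near-identical copies are hard to separate, those on opposite strands only if counting ignored strand. Among the genes named, TP73, TP53INP1, CCNE2, XRCC3, FANCA, CHAF1A, FEN1, GLMP, TGM2 and others overlap a gene with a sizeable count of its own, and CEP295NL, AHRR, CFAP251 and YPEL1 one with several times more.

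Groups, experiments and cell numbers were taken from the sample titles. The 2 libraries of a group within an experiment differed far beyond counting noise (chi-square per degree of freedom from 63.6 to 195), so neither is a copy of the other. Libraries of different groups or experiments were not compared in this way. Whether the 2 experiments used separately thawed cultures is not stated, so the p-values measure the spread between these libraries. With depths of 24715999 to 56877328 counts, counting error is small for genes at 5 CPM or more, and the number of lines limits the precision.

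Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by group, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, on 16428 genes. The 5-FU response of each genotype and their difference were fitted on all 16 libraries with a term for experiment. The genotype comparisons under DMSO and 5-FU were fitted on counts summed per line over both experiments, with the lines taken by label, as 8 sums and 17476 genes. Standard errors are the absolute log2 fold change divided by the root of the F statistic. CPM values use TMM-scaled library sizes. The response of the p53 target list was the mean over members of log2 CPM (prior count 2) under 5-FU minus DMSO of the same line and experiment, tested with an exact two-sided permutation test over all pairs. A total of 28 gene lists, among them markers of epithelial, blood and neural cells, were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists within a comparison. Of 140 list tests 62 passed, and 19 of these held with an estimated correlation, all in the same direction. The lists of epithelial, blood and neural markers passed camera in no comparison (lowest adjusted p = 0.115, for the epithelial list in the W329G response), though single members were called.

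The genes named were set by a rule fixed before the data were examined: MDM2 and CDKN1A among the genes always named; the 8 largest increases and the 8 largest decreases with adjusted p under 0.05, a mean of at least 5 CPM and the same sign in every pair (or experiment); and the 3 called members with the smallest p of each list that passed camera in its direction, leaving out clone names. Called members of lists with few calls are named besides, after their values were seen. Not every gene under the rule is printed, and a few items are not reported here.

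Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts (at least 1 read), lines as blocks, each experiment alone, no experiment term, an absolute log2 fold change of at least 1, sums per line or single libraries, limma-voom with the line as random block, prior count 0.5, the median over members, fry, and leaving out each pair or line. Cell numbers name lines of the same genotype, so DMSO and 5-FU libraries of a number and experiment were paired: within an experiment the difference between the lines correlated between treatments across genes with r of 0.487 and 0.597 in WT and 0.708 and 0.632 in W329G. Added after seeing the data were sums with the cell numbers exchanged in experiment 2, with and without a term per line, fits without mitochondrially encoded genes, genes chosen with a term per line for the attenuation, limma-voom with exchanged numbers, and the permutation of pairs within experiments.

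The steps were tested on simulated counts with the real depths, each gene's mean over all libraries and the dispersion trend. The 200 planted genes were drawn from genes of at least 5 CPM, so the recovery holds for such genes. For the WT response (16097 genes) 79% of genes planted at 2-fold and 100% at 4-fold were recovered, for the W329G response (16110 genes) 79% and 100%, for the difference (16110 genes) 53% and 98%, and for the genotype comparisons 82% and 100% under DMSO (16418 genes) and 83% and 100% under 5-FU (16425 genes). False calls made up 3.2% to 5.6% of the calls. A list planted at 1.5-fold passed camera, and 1 of 19 lists that share no planted gene passed too. These simulations hold no differences between lines or between experiments. Figures were drawn with matplotlib.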

Results

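The transcriptomes of U2OS cells, a human osteosarcoma line with wild-type p53, were measured by poly-A RNA-seq in unedited cells (WT) and in cells edited with CRISPR/Cas9 to carry MDM2 W329G. MDM2 is the E3 ubiquitin ligase that keeps p53 low and is itself a p53 target gene, and W329G replaces a tryptophan in its central acidic and zinc finger region. Each genotype was present as 2 lines, called cells 1 and cells 2, and each line was treated for 24 h with DMSO or with 50 µM of 5-fluorouracil (5-FU), a pyrimidine analog that blocks thymidylate synthase and disturbs ribosomal RNA processing. The design was carried out in 2 experiments that were sequenced by different vendors, which gave 16 libraries in 4 groups of 4. Replicates 1 and 2 are cells 1 and 2 of experiment 1, and replicates 3 and 4 are cells 1 and 2 of experiment 2. Total counts per library ran from 24715999 to 56877328. Mitochondrially encoded genes took between 7.14% of the joined counts, in W329G DMSO replicate 1, and 31.85%, in WT 5-FU replicate 1. The series asks how the W329G change alters the p53 response, and sets the genotypes against each other under DMSO and under 5-FU.

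The edited gene was read first. MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686 on the plus strand in the coordinates of the experiment 1 files) stood at 60.9 ± 18.4 CPM (SD, n = 4) in WT cells under DMSO and at 229 ± 42.5 CPM under 5-FU. In W329G cells it stood at 72.8 ± 31.8 CPM under DMSO and at 75.2 ± 19.4 CPM under 5-FU. Within experiment 1 the WT means were 45.1 and 197 CPM and the W329G means 51.3 and 66.6 CPM, and within experiment 2 they were 76.7 and 261 CPM against 94.4 and 83.9 CPM. A count per gene does not show the edited codon, so these values do not check the genotype labels.

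CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21, rose from 118 ± 37.7 to 679 ± 336 CPM (SD, n = 4) in WT cells. In W329G cells it measured 94 ± 33.8 CPM under DMSO and 155 ± 66.8 CPM under 5-FU.

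**Figure D1:**
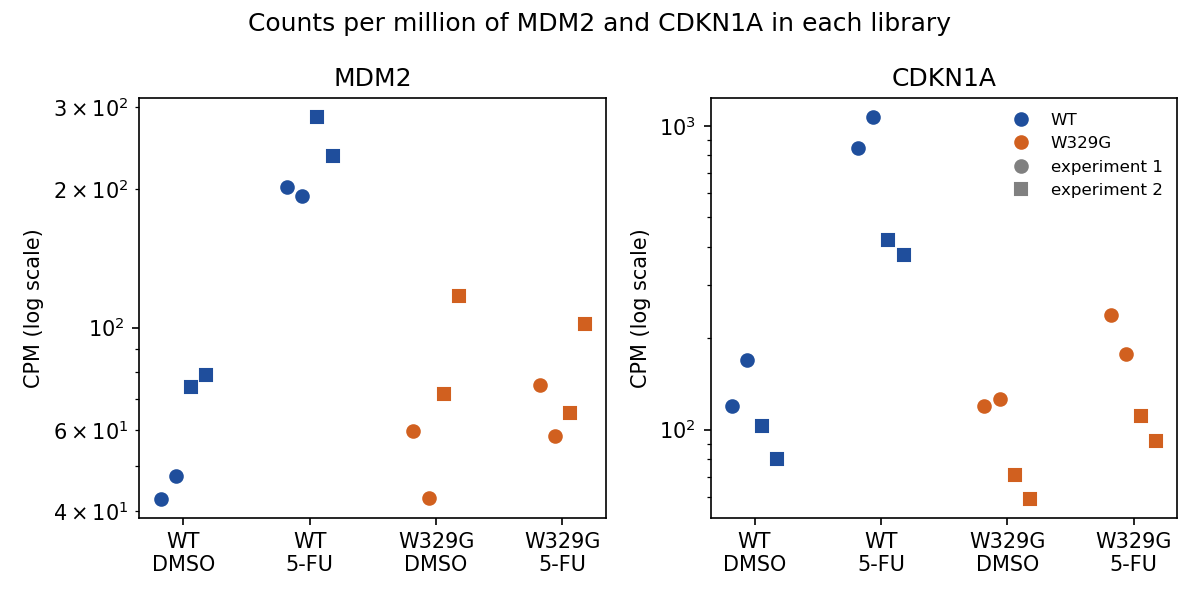
CPM, the TMM-scaled count rate (log scale), of MDM2 and CDKN1A in each of the 16 libraries, by genotype and treatment (blue, WT; orange, W329G; circles, experiment 1; squares, experiment 2; no error bars are drawn). MDM2 under 5-FU lay between 193 and 286 CPM in the WT libraries and between 58.1 and 102 CPM in the W329G libraries.

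In WT cells, 5-FU raised the p53 program. Of 103 measured p53 target genes 72 rose and 1, TNFAIP8, fell (adjusted over the list alone, 85 rose and 1 fell), with a median log2 change of 0.98. Among the strongest were TP53INP1 (log2 fold change 2.46 ± 0.15 SE), CDKN1A (2.43 ± 0.17), the death receptor gene FAS (2.34 ± 0.19), the antiproliferative gene BTG2 (2.21 ± 0.18) and MDM2 (1.95 ± 0.19). Among genes of at least 5 CPM, the largest increases outside the list were those of the adhesion gene NECTIN4 (3.50 ± 0.29), the inositol phosphatase gene INPP5D (3.12 ± 0.31), TSPAN11 (3.11 ± 0.29) and the riboflavin transporter gene SLC52A1 (2.77 ± 0.39). The stress cytokine gene GDF15, a member of the list, rose by a log2 fold change of 2.77 ± 0.56.

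By function, in lists of p53-linked genes that overlap the full list in part, 9 of 17 apoptosis genes rose, such as TNFRSF10B (1.30 ± 0.13), while 8 did not pass. Of 17 arrest and DNA repair genes 12 rose, among them RRM2B (1.83 ± 0.15), the p53-induced ribonucleotide reductase subunit, and 1 fell, FANCC. Of 15 metabolic p53 targets 9 rose, among them SESN1 (1.76 ± 0.15), FDXR (1.69 ± 0.17) and FBXO22 (0.99 ± 0.11). The camera test placed all 4 of these lists above the other genes, with adjusted p = 3.66e-81 for the full list, and all 4 calls held with an estimated correlation (adjusted p = 4.66e-06 for the full list).

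The replication genes fell. Of 47 genes of G1/S and DNA replication 45 fell (all 47 adjusted over the list alone), with a median log2 change of -1.16. The replicative helicase gene MCM4 (log2 fold change -1.81 ± 0.28), the cyclin gene CCNE2 (-1.73 ± 0.24), the chromatin assembly gene CHAF1A (-1.52 ± 0.13), the flap endonuclease gene FEN1 (-1.48 ± 0.13) and GINS2 (-1.44 ± 0.13) were among them. Of 27 DNA damage repair genes 19 fell, including BRCA1 (-1.31 ± 0.13) and MRE11 (-0.80 ± 0.11). Camera gave adjusted p = 1.39e-96 for G1/S and 2.33e-24 for repair, and p = 0.000112 and 0.00278 with an estimated correlation. Other large decreases were those of FAM111B (-2.33 ± 0.28), SPSB4 (-2.16 ± 0.49), the lipase gene LPL (-1.95 ± 0.58), PDE9A (-1.84 ± 0.47), AHRR (-1.78 ± 0.31) and the ribosomal protein paralog RPL22L1 (-1.76 ± 0.20).

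Lists tied to the drug and to proliferation moved less. Of 24 fluoropyrimidine and pyrimidine metabolism genes 7 fell, among them the ribonucleotide reductase genes RRM2 (-1.63 ± 0.17) and RRM1 (-0.97 ± 0.13) and the uracil glycosylase gene UNG (-1.15 ± 0.15), and 2 rose, RRM2B and SMUG1 (camera adjusted p = 0.0017, 0.0531 with an estimated correlation). RRM1, RRM2 and UNG are also in the G1/S list and RRM2B is in the p53 list, here and below. Of 46 G2/M genes 17 fell (35 adjusted over the list alone), and all 46 had negative values. Among the 17 were NCAPH (-0.99 ± 0.15), HMMR (-0.81 ± 0.15) and CDK1 (-0.73 ± 0.13). The G2/M list gave camera adjusted p = 1.2e-17 but p = 0.0827 with an estimated correlation. Of 24 NF-kB and inflammatory genes 5 rose, among them BIRC3 (1.60 ± 0.35), IL11 (0.98 ± 0.21) and TNFAIP2 (0.86 ± 0.21), with adjusted p = 0.000619, and p = 0.0827 with an estimated correlation. Of 30 ATF4 stress response genes 6 fell, including ATF4 (-0.83 ± 0.12) and PCK2 (-1.17 ± 0.24), and 2 rose, ATF3 and SESN2, which are also p53 targets (adjusted p = 0.000189, 0.358 with an estimated correlation). Of 25 glycolysis genes 0 passed the edgeR test (adjusted p = 0.214 for the list, 0.631 with an estimated correlation, and 0 adjusted over the list alone).

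Biosynthetic lists fell with a minority of members past the threshold. Of 17 enzymes of the pentose phosphate and serine-folate pathways 5 fell, including SHMT2 (-0.91 ± 0.11) and PGD (-0.75 ± 0.12), with camera adjusted p = 8.49e-07 and p = 0.0817 with an estimated correlation. Of 25 cholesterol synthesis genes 6 fell, among them EBP (-0.79 ± 0.15) and SQLE (-0.69 ± 0.11), with p = 0.198 with an estimated correlation. Of 24 unfolded protein and heat shock genes 5 fell, among them HSPA8 (-1.22 ± 0.15), with p = 0.267 with an estimated correlation. Of 54 ribosome biogenesis genes 4 fell, including NOP58 (-0.71 ± 0.19) and NCL (-0.51 ± 0.13), and of 19 MYC targets 3 fell, HSPE1, HSPD1 and PA2G4, and 1 rose, with p = 0.526 and 0.298 with an estimated correlation. Higher were 2 of 11 survival factor genes, BCL2L1 (1.07 ± 0.15) and BIRC3, and 1 of 20 autophagy genes, DRAM1 (1.60 ± 0.15), with p = 0.358 and 0.0817 with an estimated correlation.

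In total 1443 of 16428 tested genes passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 586 higher and 857 lower, and 1423 of these had the same direction within each experiment. With the lines paired as blocks the count was 4067 (1912 higher, 2155 lower), which included all 1443. Experiment 1 alone gave 205 genes and experiment 2 alone 0 (1751 at an unadjusted p under 0.05, and 393 by DESeq2), and leaving out the pair of WT replicate 1, 2 or 4 gave 751, 663 or 660. Without a term for experiment the count was 401, and with line sums whose numbers are exchanged in experiment 2, chosen after seeing the data, 103 (54 higher, 49 lower). With an absolute log2 fold change of at least 1 the count was 412, with the balance of directions turned as well, to 244 higher and 168 lower. Of 56 called genes reported under the naming rule, 43 kept their call in every fit without a WT pair and 27 with exchanged sums. Those exchanged sums leave the treatments of a line unpaired. With a term per line they gave 4812 genes, which included 1442 of the 1443.

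In W329G cells, 5-FU changed fewer genes and, in the fit that does not pair the lines, left most p53 targets short of the threshold. The mean response of the p53 list was small but positive in each pair, at 0.231, 0.197, 0.085 and 0.104 in replicates 1 to 4. Of 103 p53 targets 1 rose, the exonuclease gene AEN (0.62 ± 0.13), and 1 fell, CCNG1 (adjusted over the list alone, 4 rose and 1 fell). The log2 change was 0.70 ± 0.16 for CDKN1A (edgeR adjusted p = 0.0605) and 0.10 ± 0.19 for MDM2 (adjusted p = 0.882), and with lines as blocks the adjusted p was 0.00531 for CDKN1A and 0.626 for MDM2. Within experiments the MDM2 change was 0.37 in experiment 1 and -0.18 in experiment 2. The p53 list had a median log2 change of 0.13 (camera adjusted p = 0.00664, 0.383 with an estimated correlation).

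Of the genes called in W329G cells 97 of 129 were lower, but with lines as blocks the directions were nearly even, at 844 higher and 947 lower. Among genes of at least 5 CPM, large decreases were those of RPL22L1 (log2 fold change -1.68 ± 0.20), the kinase gene PSKH1 (-1.52 ± 0.18), the inositol monophosphatase gene IMPA2 (-1.48 ± 0.19), the calcium pump gene ATP2A3 (-1.43 ± 0.23), NPTXR (-1.30 ± 0.17) and the mitochondrial enzyme gene PCK2 (-1.29 ± 0.24). Others were those of TTC13 (-1.21 ± 0.25) and of YPEL1 (-1.52 ± 0.29), which shares its locus with the more abundant PPIL2. Increases within the same limit were led by CEP295NL (2.86 ± 0.32), which lies inside TIMP2, a gene with far more counts, so that its reads may be hard to separate. PEAR1 (1.40 ± 0.29), the coactivator gene RBM14 (1.16 ± 0.13), P2RX6 (1.09 ± 0.22), CFAP251 (1.06 ± 0.17, overlapped by the more abundant PSMD9), the water channel gene AQP1 (1.04 ± 0.22), MARCHF4 (1.02 ± 0.21) and ARID5A (0.95 ± 0.20) rose as well.

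Several groups shifted as lists in W329G cells. In the fit that does not pair the lines, each had few members past the threshold when adjusted over all genes. Of 78 cytosolic ribosomal protein genes 2 fell, RPL3 (-1.10 ± 0.15) and RPL10A (-0.97 ± 0.12), and 77 had negative values (camera adjusted p = 2.7e-21, 0.197 with an estimated correlation). Of 46 G2/M genes 3 fell (27 adjusted over the list alone), HMMR (-0.71 ± 0.15), KIF20A (-0.69 ± 0.12) and PLK1 (-0.59 ± 0.12). The G2/M list gave camera adjusted p = 7.9e-23 and p = 0.142 with an estimated correlation. The mean of the G2/M list was negative in each pair, at -0.432, -0.224, -0.438 and -0.549 in replicates 1 to 4. Of 24 genes of the unfolded protein and heat shock list 3 fell, the chaperone gene HSPA8 (-1.15 ± 0.14), XBP1 (-0.90 ± 0.15) and HERPUD1 (-0.70 ± 0.15), with p = 0.142 with an estimated correlation. Of 24 NF-kB genes 1 rose, TNFAIP3 (1.00 ± 0.21), with p = 0.142 with an estimated correlation. No list passed in W329G cells with an estimated correlation. Of 47 G1/S genes 0 passed the edgeR test (1 adjusted over the list alone), with a median log2 change of -0.08 (camera adjusted p = 0.0467, 0.678 with an estimated correlation). Of 25 glycolysis genes 1 fell, PGM1 (camera adjusted p = 0.125). Of 30 ATF4 genes 3 fell, PCK2, ATF4 (-0.57 ± 0.12) and SHMT2 (-0.53 ± 0.11), and of 16 histone genes 1 fell, H2BC21 (-1.10 ± 0.24), with p = 0.383 and 0.42 with an estimated correlation. The histone list averaged -1.17 and -0.521 in the pairs of experiment 1 but -0.0214 and 0.0968 in those of experiment 2, though H2BC21 fell in both (-1.37 and -0.82), and the ribosomal protein list averaged -0.592, -0.0949, -0.296 and -0.195 in replicates 1 to 4. Differences between these pairs were not tested. Camera also placed pentose phosphate, oxidative phosphorylation and cholesterol genes lower, with 1, 0 and 0 members past the edgeR threshold and p = 0.328, 0.383 and 0.383 with an estimated correlation. Ribosomal protein, heat shock and histone genes have near-identical copies that can share reads, so their values are uncertain. The libraries hold poly-A RNA, so histone counts here and below cover only transcripts with a poly-A tail.

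In total 129 genes passed, 32 higher and 97 lower, and with the lines as blocks 1791 passed (844 higher, 947 lower), including all 129. Leaving out the pair of W329G replicate 1, 2, 3 or 4 gave 22, 14, 20 or 11 genes, DESeq2 gave 553, and without a term for experiment the count was 7. Either experiment alone gave 0 by edgeR (1106 and 880 at an unadjusted p under 0.05, and 82 and 42 by DESeq2), line sums by label gave 73, and sums with exchanged numbers 0 (1183 unadjusted, and 112 by DESeq2). With a minimum absolute log2 fold change of 1 the count was 42. Of 29 called genes under the naming rule, 9 kept their call in every fit without a W329G pair and 0 with exchanged sums. These sums, too, leave the treatments of a line unpaired. With a term per line they gave 2598 genes, including all 129. Among the genes called in WT, 68 were also called in W329G, 66 of them in the same direction, where 6.2 would share a direction if the lists were independent. Across all tested genes, which are not independent replicates, the log2 changes of the genotypes correlated with r = 0.38.

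The difference between the responses was tested directly. The mean response of the p53 target list was 1.04 ± 0.13 (SD, n = 4 line-and-experiment pairs) in WT and 0.154 ± 0.0709 in W329G on the log2 scale, a difference of -0.889 with p = 0.0286 in an exact two-sided permutation test of the pairs, the smallest p that 70 assignments allow. The responses differ between the experiments, and with pairs permuted only within an experiment, added after seeing the data, the exact p was 0.0556, the smallest that 36 assignments allow, so the call is lost there. All 4 WT pairs lay above all 4 W329G pairs, by a gap of at least 0.696. Within experiment 1 the difference was -0.921 and within experiment 2 it was -0.857, each with p = 0.333 in an exact permutation test, the smallest that 2 pairs against 2 allow. The pairs of a genotype come from 2 lines, so the test does not count 4 independent clones.

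**Figure D2:**
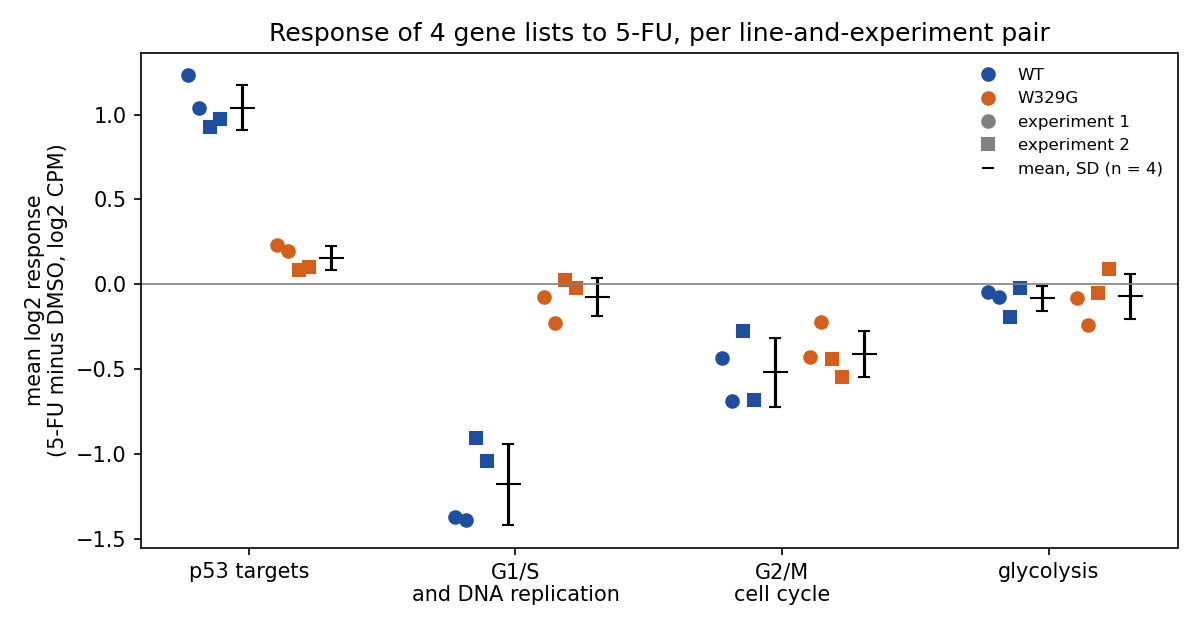
Mean log2 response (5-FU minus DMSO of the same line and experiment, log2 CPM, prior count 2) of 4 gene lists, 1 point per line-and-experiment pair (blue, WT; orange, W329G; circles, experiment 1; squares, experiment 2), with the mean and SD of 4 pairs in black. The p53 list averaged 1.04 in WT and 0.154 in W329G, G1/S -1.18 and -0.0755, G2/M -0.52 and -0.411, and glycolysis -0.0836 and -0.0717.

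Gene by gene, 30 of 103 p53 targets had a lower response in W329G and 0 a higher one (adjusted over the list alone, 63 and 0). The difference of log2 changes was -2.58 ± 0.20 for TP53INP1, -2.01 ± 0.26 for FAS, -1.97 ± 0.24 for BTG2, -1.85 ± 0.27 for MDM2, -1.83 ± 0.21 for both RRM2B and SESN1, -1.73 ± 0.23 for CDKN1A, -1.61 ± 0.23 for FDXR and -1.16 ± 0.17 for TP53I3. Outside the list, among genes of at least 5 CPM, NECTIN4 (-2.91 ± 0.40), INPP5D (-2.87 ± 0.42), TSPAN11 (-2.36 ± 0.40), PIK3IP1 (-2.23 ± 0.40) and SUGCT (-2.10 ± 0.45) had the largest lower responses. Of the 17 apoptosis targets 7 were lower, of the 17 arrest targets 6 and of the 15 metabolic targets 4. Camera gave adjusted p = 3.57e-76 for the full list and p = 8.25e-06 with an estimated correlation, and the calls of the 3 functional lists held too.

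The replication genes differed in the opposite sense. Of 47 G1/S genes 32 had a higher value in W329G, where they did not fall as in WT (44 adjusted over the list alone), among them E2F2 (1.75 ± 0.28), CHAF1A (1.44 ± 0.18), CDC45 (1.31 ± 0.19) and CCNE1 (1.27 ± 0.17). The list averaged -1.18 ± 0.24 (SD, n = 4) in WT and -0.0755 ± 0.11 in W329G, with p = 0.0286 in the exact permutation test of the pairs and 0.0556 with pairs permuted within experiments. Of 27 repair genes 8 were higher, including BRCA1 (1.23 ± 0.18), FANCA (1.19 ± 0.22) and XRCC3 (1.03 ± 0.18). Camera gave adjusted p = 3.17e-97 and 4.69e-24 for these lists, and p = 0.000145 and 0.00285 with an estimated correlation. Of 24 pyrimidine metabolism genes RRM2 (1.38 ± 0.24) and UNG (0.98 ± 0.22) were higher and RRM2B was lower (camera adjusted p = 0.000497, 0.0258 with an estimated correlation). Of 20 autophagy and lysosome genes DRAM1 (-1.38 ± 0.21) and WIPI1 (-0.95 ± 0.22) were lower (camera adjusted p = 0.000276, 0.00821 with an estimated correlation). RRM2 and UNG are also G1/S members, and RRM2B and DRAM1 are p53 list members. The pyrimidine and autophagy calls are therefore not independent of those lists. Within the same limit, the largest higher responses were those of C1QTNF2 (2.01 ± 0.29), FAM111B (1.88 ± 0.38), the p53 family gene TP73 (1.86 ± 0.42), CCNE2 (1.79 ± 0.32), HUNK (1.69 ± 0.25), TUBA3C (1.59 ± 0.25) and EXO1 (1.58 ± 0.30).

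For other lists no difference was called or the call was lost with an estimated correlation. The G2/M list averaged -0.52 ± 0.202 (SD, n = 4) in WT and -0.411 ± 0.136 in W329G, with p = 0.457 in the exact permutation test, and 0 of 46 members passed the edgeR test (1 adjusted over the list alone, camera adjusted p = 0.207). The glycolysis list averaged -0.0836 ± 0.0744 and -0.0717 ± 0.134, with p = 0.971 in the exact permutation test, and 0 of 25 members passed (camera adjusted p = 0.932). Ribosomal protein genes were lower as a list with 0 of 78 passing (adjusted p = 7.54e-08, 0.53 with an estimated correlation), with the largest W329G decrease in replicate 1 (-0.592), histone genes were lower with 0 of 16 passing (adjusted p = 0.00155, 0.566 with an estimated correlation), and ribosome biogenesis genes were higher with 0 of 54 passing (adjusted p = 0.00322, 0.566 with an estimated correlation).

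In total 198 genes differed in their response by edgeR (461 by DESeq2), 114 with a higher value in W329G and 84 with a lower one, and 190 of them were also called in WT. With the lines as blocks 1009 passed (591 higher, 418 lower), including all 198. Leaving out WT replicate 1 or 2 gave 92 or 86 genes, leaving out W329G replicate 1, 2, 3 or 4 gave 100, 109, 113 or 111, without a term for experiment the count was 21, and line sums by label gave 127. The balance of directions is not stable: it turned to 6 higher and 15 lower without the term, 60 and 67 with line sums, 41 and 51 or 42 and 44 without WT replicate 1 or 2, and 45 and 55 or 52 and 59 without W329G replicate 1 or 4. Either experiment alone gave 0 by edgeR (818 and 638 at an unadjusted p under 0.05, and 144 and 48 by DESeq2), and sums with exchanged numbers gave 0 (859 unadjusted, 128 by DESeq2) without and 1276 with a term per line. Of 33 called genes under the naming rule, 22 kept their call in every fit without a pair.

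**Figure D3:**
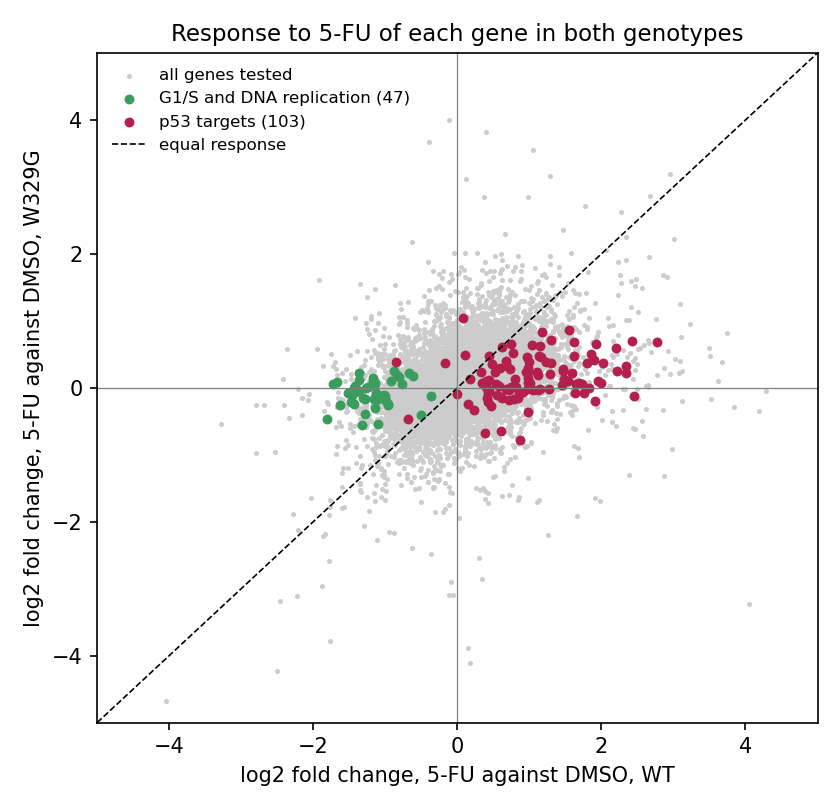
Log2 fold change of each tested gene after 5-FU in WT (x axis) and in W329G (y axis), with 103 p53 target genes in red, 47 G1/S and DNA replication genes in green and all genes in grey; the dashed line marks equal responses, and 4 genes lie outside the axes at -5 and 5. The p53 genes had a median of 0.977 on the x axis and 0.125 on the y axis, and the G1/S genes -1.16 and -0.084.

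As a reading of the responses in libraries that did not choose the genes, the 205 genes called in WT in experiment 1 were read in experiment 2. Their median response in the WT direction was 1.03 on the log2 scale in WT and 0.151 in W329G, and 200 of them (97.6%) had a smaller response in W329G. The reverse choice gave no genes, since experiment 2 alone called 0. With a term per line in the choosing experiment, added after seeing the data, 79.3% of 3435 genes from experiment 1 and 80.1% of 2361 genes from experiment 2 had a smaller response in W329G in the other experiment. Genes chosen for a response in WT favour WT if any responses belong to a genotype or line. Chosen in W329G instead, also after seeing the data and with a term per line, 49.2% of 1630 genes from experiment 1 and 37.7% of 913 from experiment 2 had a smaller response in W329G in the other experiment. Their median responses there were 0.272 in WT and 0.314 in W329G, and 0.246 and 0.365. Each choice favours the genotype it is made in, so these shares do not measure the attenuation free of the choice.

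Under DMSO the genotypes differed in a set of genes whose size depends on the fit, and the p53 list did not pass camera. Of 104 p53 targets 1 was higher in W329G, CPE, and 0 were lower (camera adjusted p = 0.706). The log2 difference was 0.19 ± 0.14 for MDM2 and -0.31 ± 0.16 for CDKN1A, with edgeR adjusted p of 0.502 and 0.339. The lysosomal membrane gene GLMP was lower (log2 difference -4.56 ± 0.33), at 10.9 ± 2.75 CPM (SD, n = 4) in WT and 0.472 ± 0.191 CPM in W329G. The transglutaminase gene TGM2 differed by -2.72 ± 0.12, CT45A1, a cancer-testis gene with near-identical copies, by -3.72 ± 0.38, C6orf15 by -3.50 ± 0.39, the imprinted gene PEG10 by -2.22 ± 0.36, the protease gene MMP9 by -1.89 ± 0.26, SLC38A3 by -2.35 ± 0.38 and ROR1 by -1.82 ± 0.15. Higher in W329G were PAPPA2 (2.96 ± 0.53), the spectrin gene SPTAN1 (1.90 ± 0.16), CLEC2B (1.76 ± 0.17), the collagen gene COL3A1 (1.58 ± 0.20), EYA1 (1.55 ± 0.15), SHOC1 (1.62 ± 0.18), BMP6 (1.47 ± 0.28) and GABARAPL1 (1.32 ± 0.13).

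Counts of list members under DMSO are those by label. With exchanged numbers only GLMP and ZNF154 passed over all genes, neither of them in a list. Of 21 called genes under the naming rule, 1 kept its call there. By label, 6 of 18 replication-dependent histone genes were lower under DMSO, including H2BC12 (-1.25 ± 0.15), H1-2 (-0.99 ± 0.14) and H2BC21 (-0.98 ± 0.16), with camera adjusted p = 7.92e-11 but p = 0.674 with an estimated correlation. Ribosomal protein genes were higher as a list with 1 of 78 passing, RPL23A (0.99 ± 0.18, camera adjusted p = 3.89e-11), G2/M genes with 0 of 46 (adjusted p = 4.09e-06) and NRF2 target genes with 1 of 20, the malic enzyme gene ME1 (0.68 ± 0.12, adjusted p = 0.00094). ATF4 genes (0 of 30) and oxidative phosphorylation genes (0 higher and 2 lower of 55, NDUFB10 and SDHA) were higher as lists, and cholesterol genes (0 of 25) lower. Each of these lists gave p = 0.674 with an estimated correlation. Within the osteoblast and matrix list, which was not past the threshold, COL3A1, COL5A2 (0.67) and SPP1 (1.07) were higher. Of 25 glycolysis genes 0 passed (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0863, and 0.0477 with exchanged numbers).

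The count under DMSO was 249 of 17476 genes, 79 higher and 170 lower, on counts summed per cell number as labelled over both experiments (edgeR, 2 numbers per genotype). It rests on which libraries are summed: with the cell numbers exchanged in experiment 2 it was 2, GLMP and ZNF154, a zinc finger gene named here after its values were seen, and leaving out either W329G line (replicate 1 or 2) gave 1, TGM2. It was 137 without WT line 1, 2308 without WT line 2, 567 with the cell number as a block, 153 on single libraries, 922 without a filter, 1209 by DESeq2, 115 with an absolute log2 fold change of at least 1, 0 in experiment 1 (809 at an unadjusted p under 0.05, 39 by DESeq2) and 4 in experiment 2 (GLMP, TGM2, ZNF154 and PAPPA2).

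Under 5-FU the genotypes differed widely on sums by label, with 2507 genes past the edgeR threshold, but 222 with the numbers exchanged in experiment 2. Counts of list members under 5-FU are those by label. Of 104 p53 targets 65 were lower in W329G and 0 higher (79 and 3 adjusted over the list alone), including TP53INP1 (-2.35 ± 0.16), BTG2 (-2.09 ± 0.15), the fucosidase gene FUCA1 (-2.06 ± 0.18), CDKN1A (-2.01 ± 0.17), RRM2B (-1.98 ± 0.16), FAS (-1.90 ± 0.13), INKA2 (-1.78 ± 0.11), ZMAT3 (-1.75 ± 0.16) and MDM2 (-1.61 ± 0.15). Of 47 G1/S genes 45 were higher, led by EXO1 (2.00 ± 0.17), RRM2 (1.94 ± 0.13) and CHAF1B (1.91 ± 0.15). Of 27 repair genes 18 were higher, among them RAD51AP1 (1.69 ± 0.14) and BARD1 (0.99 ± 0.11).

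Other groups under 5-FU divided as follows. Of 18 histone genes 11 were lower, such as H2BC21 (-2.33 ± 0.17), H2BC12 (-2.06 ± 0.15) and H1-2 (-1.84 ± 0.15). These counts cover only histone transcripts with a poly-A tail. Of 24 pyrimidine genes 10 were higher, including DUT (1.11 ± 0.12) and RRM1 (0.91 ± 0.11), and 1 was lower, RRM2B. Of 46 G2/M genes 12 were higher, among them FOXM1 (0.95 ± 0.11), KIF11 (0.94 ± 0.14) and NCAPH (0.91 ± 0.14). Of 30 ATF4 genes 7 were higher, including CHAC1 (2.00 ± 0.32) and SLC7A11 (1.15 ± 0.23), and 1 was lower, SESN2. Of 25 glycolysis genes 4 were higher, ENO1 (0.41 ± 0.11), ENO2 (0.51 ± 0.14), GAPDH (0.61 ± 0.15) and TPI1 (0.51 ± 0.14), and 2 were lower, PGM1 (-0.82 ± 0.12) and PFKFB4 (-0.58 ± 0.15), with camera adjusted p = 0.205 for the list. Camera passed p53 targets (adjusted p = 3.47e-51), G1/S (5.49e-67) and repair (2.6e-20), which gave p = 0.0155, 0.0155 and 0.0367 with an estimated correlation. It passed histones (3.63e-19), pyrimidine metabolism (1.12e-06), G2/M (2.16e-05) and ATF4 (0.00116) as well, which gave p = 0.0595, 0.0929, 0.489 and 0.507 with an estimated correlation.

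Smaller list shifts under 5-FU ended with an estimated correlation. Of 17 pentose phosphate and folate enzymes 4 were higher, including MTHFD1 (0.94 ± 0.23), of 54 ribosome biogenesis genes 7, including NOP2 (0.70 ± 0.12), of 20 MYC targets 4, including TFRC (0.84 ± 0.13), and of 20 NRF2 targets 5, including PIR (1.02 ± 0.18), TXNRD1 (0.71 ± 0.11) and ME1 (0.80 ± 0.12). With an estimated correlation these gave adjusted p = 0.489, 0.507, 0.356 and 0.255. Lower were 5 of 20 autophagy and lysosome genes, among them DRAM1 (-1.49 ± 0.13), while 1, GABARAPL1 (1.09 ± 0.13), was higher, and 4 of 24 unfolded protein genes, among them EDEM1 (-0.88 ± 0.17), with camera adjusted p = 0.255 and 0.507 with an estimated correlation. Among cell type markers, whose lists did not pass, KRT5 (-3.70 ± 0.69), SYP (-1.72 ± 0.35), SOX2 (-1.45 ± 0.38) and KRT8 (-1.08 ± 0.28) were lower and GAP43 (1.21 ± 0.27) and SNAP25 (0.78 ± 0.22) higher, named after their values were seen.

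Among genes of at least 5 CPM, the largest single differences under 5-FU were those of GLMP (-4.42 ± 0.32), C6orf15 (-4.27 ± 0.40), IGFL3 (-4.00 ± 0.41), MYH16 (-3.99 ± 0.46), CT45A1 (-3.95 ± 0.38), NECTIN4 (-3.76 ± 0.28), SERPINB5 (-3.08 ± 0.39) and TGM2 (-3.07 ± 0.12). In the other direction stood the ephrin gene EFNA5 (2.06 ± 0.19), SUSD5 (2.03 ± 0.32), EXO1, LPL (1.99 ± 0.26), SPSB4 (1.99 ± 0.37) and the receptor gene GPR19 (1.98 ± 0.26). With exchanged numbers, GLMP (adjusted p = 0.00591), NECTIN4 (0.0103), TGM2 (0.0112), CDKN1A (0.0142), MDM2 (0.037), RRM2 (0.0217) and EFNA5 (0.0433) remained past the threshold, while C6orf15 (0.0639), CT45A1 (0.0746), IGFL3 (0.15), MYH16 (0.0806), SERPINB5 (0.313) and SPSB4 (0.2) did not.

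In total 2507 of 17476 genes passed under 5-FU by edgeR, 1268 higher and 1239 lower. With the numbers exchanged in experiment 2 the count was 222 (102 higher, 120 lower), all among the 2507, and leaving out W329G line 1 or 2 gave 330 (150 higher, 180 lower) or 179 (69 higher, 110 lower). Of 58 called genes reported under the naming rule, 28 kept their call in every fit without a line and 25 with exchanged numbers. Experiment 1 alone gave 421 and experiment 2 alone 30, and an absolute log2 fold change of at least 1 left 902, 343 higher and 559 lower. As each genotype has 2 lines, the comparisons of genotype measure 2 edited lines against 2 unedited ones. The sums, and the lines left out, go by label. If the numbers were exchanged between the experiments, each sum by label mixes both lines of a genotype. Calls and SEs by label then understate the spread between lines. The common dispersion was 0.0274 with sums by label and 0.0696 with exchanged numbers.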

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

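The tests on drift of the lines, on a single wrong label, on the amount of 5-FU reaching the cells, on clonal differences, on a lost chromosome segment and on TMEM79 were chosen only after the results they measure were seen.

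Genes and lists stand here because their 5-FU responses differed between the genotypes in a test of the difference itself: 198 genes by edgeR, the p53 target list by -0.889 and the G1/S and DNA replication list by 1.1 on the log2 scale. Smaller responses in W329G were those of NECTIN4 (-2.91), INPP5D (-2.87), TP53INP1 (-2.58), TSPAN11 (-2.36), PIK3IP1 (-2.23), SUGCT (-2.10), FAS (-2.01), BTG2 (-1.97), MDM2 (-1.85), RRM2B (-1.83), SESN1 (-1.83), CDKN1A (-1.73), FDXR (-1.61), DRAM1 (-1.38), TP53I3 (-1.16), WIPI1 (-0.95) and FBXO22 (-0.84). Higher values in W329G were those of UNG (0.98), XRCC3 (1.03), FANCA (1.19), BRCA1 (1.23), CCNE1 (1.27), CDC45 (1.31), RRM2 (1.38), CHAF1A (1.44), EXO1 (1.58), TUBA3C (1.59), HUNK (1.69), E2F2 (1.75), CCNE2 (1.79), TP73 (1.86), FAM111B (1.88) and C1QTNF2 (2.01).

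Of 103 groups of 4 values tested with Dixon's rule, 3 had a value far from the others. The groups were list or gene responses of 4 pairs, or total counts and mitochondrial shares of 4 libraries. Chance gives about 1 in 20 independent groups, but most groups here are genes named for their calls and read in the same pairs. The 3 were RRM1 in WT (-0.616, others -1.1 to -1.03), IL11 in WT (0.522, others 1.07 to 1.15) and AQP1 in W329G (0.577, others 1.17 to 1.24), each in replicate 3.

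Among 4398 genes of experiment 1 that the joined comparisons do not use, 11 passed in the WT response, 10 higher and 1 lower, and 12 passed between the genotypes under 5-FU, 1 higher and 11 lower. With a line term 388 passed in the WT response (316 higher), 213 in the W329G response (168 higher) and 55 in the difference (20 higher). The 11 include the noncoding genes LNCTAM34A (2.05 ± 0.34), GAS6-AS1 (1.98 ± 0.24), PVT1 (1.21 ± 0.21) and LINC00973 (1.19 ± 0.20), named after their values were seen.

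The weaker p53 response in W329G was weighed against technical explanations. If less 5-FU reached these cells and all lists shrank by the p53 share of 0.148, G2/M would stand at -0.077, but that list averaged -0.411. The G1/S list kept a share of 0.0642 of its WT response, as lower exposure could give. Lists need not follow the dose in proportion, so these values cannot decide whether less 5-FU reached the cells. Without mitochondrially encoded genes the p53 difference was -0.897, against -0.889 with them. TMM factors already trim extreme genes, so this test had little room to move. It decides little on a few genes taking most of the counts. An effect of clones apart from the edited codon cannot be told apart from the edit, since each genotype has lines of its own, and the gap of 0.696 between the lowest WT and the highest W329G pair holds for either. The edit itself stays open as a hypothesis.

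Splits of the samples into made-up groups are too few here for a share under 0.05 once the design is kept. For the WT response 8 splits part all pairs, with 1443 genes in the real one and a highest other of 0. For the W329G response it is also 8, with 129 and 0. For the difference 18 splits keep 2 pairs of each made-up genotype in each experiment, with 198 and 0. Over all 35 splits, which ignore the pairs, the split by exchanged numbers gave 599 genes in WT and 2506 in W329G, above the real 129, which points to the line as a structure of the samples, and the highest other for the difference was 2.

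The difference between the lines of a genotype turned between the experiments, with correlations across genes of -0.19, -0.302, -0.485 and -0.568 in WT DMSO, WT 5-FU, W329G DMSO and W329G 5-FU. Of 26 genes at least 16-fold apart between the lines in experiment 1, 92.3% had the opposite sign in experiment 2. By genotype these were 20 of 21 in W329G and 4 of 5 in WT. The cell numbers may therefore have been exchanged between the experiments, with few such genes to tell it in WT. Unrelated drift of the lines would bring the correlations near 0, and the highest was -0.19. Drift along a course that the lines share could also turn the sign, so the correlations alone do not exclude drift. The DMSO and 5-FU groups of a genotype come from the same lines, so the 4 correlations are not independent. A single wrong label would turn 1 group, and 4 turned. Which experiment carries the other numbering is open.

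GLMP, nearly silent in W329G, lies among 13 neighbours within 300 kb whose median log2 difference under DMSO was -0.145 (-0.437 to 0.0391, 0 past the edgeR threshold), which argues against loss of a chromosome segment that spans these neighbours. Their values cannot show a loss confined to GLMP. TMEM79, which overlaps GLMP on the other strand, differed by -0.0117 (SE 0.201), which argues against counts taken by that gene. No biological explanation was tested.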

How the results depend on the processing

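Sums with exchanged numbers, fits with a line term on them, limma-voom with exchanged numbers, fits without mitochondrial genes, attenuation with a line term, from either genotype, and the permutation within experiments were chosen after seeing the data. Unless a reason is given, the cause was not tested. In the order WT response, W329G response, difference, genotype under DMSO and under 5-FU, the counts were 1443, 129, 198, 249 and 2507. DESeq2 size factors kept all 5 within 1.5 times, as did leaving out mitochondrial genes.

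The DESeq2 test gave 553 (W329G), 461 (difference) and 1209 (DMSO), and no filter gave 922 (DMSO). With lines as blocks the counts were 4067, 1791 and 1009, as the pairing removes the spread between lines. The cell number as a block, which pairs nothing, gave 567 (DMSO). All 56, 29 and 33 called genes under the naming rule kept their calls with the block. Experiment 1 alone, with fewer samples, gave 205, 0, 0, 0 and 421, and experiment 2 alone 0, 0, 0, 4 and 30 (where edgeR gave 0, an unadjusted p under 0.05 gave 638 to 1751 genes and DESeq2 39 to 393). Without an experiment term the counts were 401, 7 and 21. An absolute log2 fold change of at least 1, stricter by construction, left 412, 42, 115 (DMSO) and 902 (5-FU). Sums per line gave 73 (W329G) and 127 (difference), and single libraries 153 (DMSO).

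The line numbers may be crossed: exchanged sums gave 103, 0, 0, 2 and 222, with a term per line as block 4812, 2598 and 1276, and limma-voom 12 (DMSO) and 1078 (5-FU). Leaving out 1 pair or line gave 660 to 1178, 11 to 22, 86 to 205, 1 to 2308 and 179 to 2966; a line left alone is assumed to vary like the others.

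The p53 list difference kept its direction throughout (-0.927 to -0.827 without a pair), and was -0.921 and -0.857 in the experiments alone, where the exact test cannot pass. With pairs permuted only within experiments it stayed at -0.889 but lost its call (exact p = 0.0556, the smallest possible). Of 62 list calls 19 held with an estimated correlation. Directional fry gave 41 calls over all 140 list tests, which is not a share of the 62. The share of genes with a smaller response in W329G was 97.6%, and 79.3% and 80.1% with a line term, but 49.2% and 37.7% on genes chosen in W329G; the planned choice of genes from experiment 2 gave no value, as edgeR called 0 genes there (1751 unadjusted, 393 by DESeq2).

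Among the named values a sign change was seen in 1 that was near 0 and not called. Most named genes were chosen by their calls, part of them also by the same sign in every pair or experiment. This choice left sign changes little room, while MDM2 is always named. The MDM2 response in W329G was -0.183 in experiment 2 and -0.00912 without W329G replicate 2 (up to 0.224 without replicate 4). Of the values of named genes under alternatives, 2282 kept direction and side of the threshold, 860 lost the call, 3 gained one and 2 changed sign. With these depths the lines limit the counts more than counting error does, and simulated 2-fold differences of response in genes of at least 5 CPM were recovered at 53%.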

Other observations

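The test on clonal differences was chosen after the result was seen; no other hypothesis test is added here.

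A few immune genes moved in WT cells. TRIM22, a member of both the p53 target and the interferon list, rose (log2 fold change 1.47 ± 0.26), as did RIGI of the interferon list (0.52 ± 0.155). The antiviral gene OAS3 fell (-1.13 ± 0.21), and the interferon list of 36 genes did not pass camera (adjusted p = 0.372). The cytokine gene CSF2 rose by 2.23 ± 0.63 at low counts.

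Across the genes called in WT, 80.2% had the same sign in W329G. Genes up in WT had medians of 0.902 in WT and 0.281 in W329G, and genes down in WT had -0.692 and -0.194. These medians favour WT, where the genes were chosen.

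GLMP and ZNF154 were the 2 genes at least 4-fold lower in the highest W329G library than in the lowest WT library (with at least 2 CPM in the higher genotype), and 0 genes met the opposite. ZNF154 stood at 2.34 to 7.81 CPM in WT under DMSO and at 0.0279 to 0.461 CPM in W329G. A difference between clones could give such genes without the edit, and the gap of 0.696 in the p53 list is open in the same way.

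The hypoxia, interferon, blood, epithelial, neural and osteoblast lists did not pass camera in the fits of the report. Under alternatives, hypoxia genes passed under DMSO with exchanged numbers (adjusted p = 0.0477, but 0.674 by label with an estimated correlation), and with lines as blocks the osteoblast and matrix list passed as higher in the WT response (adjusted p = 0.0388) and as lower in the difference (0.0337). Directional fry passed it as lower in W329G under 5-FU (adjusted p = 0.018, where camera gave 0.109). With an estimated correlation and no block the block calls gave 0.358 and 0.54, and the WT pairs averaged 0.53 and 0.384 in experiment 1 but -0.113 and 0.12 in experiment 2.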
